A study of Mus musculus with 127 samples.

How the data were processed

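Ovaries of aged female mice were profiled by Lexogen QuantSeq 3′ mRNA sequencing, a method that reads near the 3′ end of polyadenylated transcripts. The 10 vehicle libraries and 3 libraries for each of 39 compounds were assigned to groups and replicate numbers by their titles. The submitters' processing notes name the read checker FastQC 1.9, the aligner STAR 2.7.9a, the quantifier RSEM 1.3.3 and the mouse genome build GRCm39. Parameters, read trimming and the annotation release are not given in the sources used here.

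Each deposited gene table holds RSEM's expected counts, which are estimates that need not be whole numbers (88.2% of the values were whole). The tables the authors deposited also give TPM values and FPKM values, which divide by an effective gene length that a 3′ method does not sample, and these were not used here. Expected counts were rounded to whole numbers before every test. RSEM divides reads that match several genes among them, so levels of pseudogenes and of genes with near-identical copies, such as Rps19-ps6, Rpl37rt, Hspa1a and Hspa1b, are uncertain, as are those of overlapping genes. Strand use in the counting is not given in the sources used here, so a gene and its antisense partner cannot be told apart.

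All tables list the same 55416 Ensembl identifiers. Of these, 52083 (94.0%), which carry 91.6% of the counts, were matched by identifier to a symbol in a GENCODE M21 gene table of an earlier build, GRCm38. That table was used for names alone, and no coordinates are given. Libraries held 3.84 to 14.9 M counts, with a median of 12.7 M. At the median total a gene with 0 counts may lie at up to 0.236 CPM (counts scaled to equal library totals), taken as 3 counts of the total, a limit that covers counting error alone. No pair of libraries of 1 group agreed within sampling noise, since the smallest chi-square per degree of freedom between them was 4.45.

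The 20464 genes kept by edgeR's filterByExpr with the group as factor were scaled by TMM and tested with edgeR 4.0.16 quasi-likelihood F tests (estimateDisp and glmQLFit with robust = TRUE, glmQLFTest) in R 4.3.3. A single fit held all libraries with 1 mean per group, so that all groups shared 1 estimate of the spread. Each compound was compared with vehicle, and a gene was called at a Benjamini-Hochberg adjusted p under 0.0500 within its comparison. The same fit gave the contrast of the mean of all compounds with vehicle, the test of any difference among the compound groups, and 10 differences between structurally related compounds. Standard errors (SE) of log2 fold changes are the fold change divided by the square root of F. Levels are TMM-scaled CPM, given as mean ± SD. A second count applied 1 adjustment over all genes and all compounds together.

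A total of 34 gene lists of pathways, ovarian cell types and neighbouring tissues were fixed before the data were examined. They were tested in each compound with limma 3.58.1 camera on log2 CPM (prior count 2), with the correlation between members estimated from the residuals and 1 adjustment over all 1326 combinations. Genes named in the text follow a rule fixed at the same time. For the 3 compounds with the most called genes these are the 12 largest and 12 smallest fold changes among called genes with at least 5 CPM, a symbol that is not a model name (Gm or Rik), and all 3 libraries on 1 side of the vehicle mean. For each other compound and each pair they are the 3 called genes with the smallest adjusted p that pass these filters (for pairs, the symbol and level filters). To these were added the 12 genes called in most compounds, 10 genes for each of the tests over all compounds, a fixed panel of 12 ovarian genes, and up to 4 members of a list whose change is described. Of the genes these rules pick, 2 are not reported here, and counts over named genes leave them out. Other genes, named where a count is small or a library stands apart, were chosen after their values were seen.

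Before the data were examined, these alternatives were set: DESeq2 1.42.0 with its own size factors, no filter on low counts, the replicate number as a block, a fit of the 2 compared groups alone, and leaving out in turn each vehicle library, or replicate 1, 2 or 3 of every compound at once; for lists also a preset correlation of 0.0100 and a prior count of 0.500. Replicate numbers do not name animals shared between groups. After the data were seen, 4 alternatives were added: leaving out replicate 2 of Chlorogenic Acid, a batch term, vehicle libraries of the same batch, and the other compounds of the same batch. The last 3 also leave out that library. The labels give no batch. Batches were found by dividing the libraries, in the order of the series, into 6 runs of alike levels of 1355 pseudogenes, gene models, histone genes, small nucleolar RNAs and mitochondrial tRNAs (8 principal components, at least 5 libraries a run). Vehicle libraries were placed in the nearest run. The number of runs was chosen after the data were seen, and other numbers moved the borders.

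The analysis was tested on simulated counts drawn with the means and library sizes of these samples. Their spread came from a set formula and not from these samples, and no library was made to fail. Only genes averaging at least 20 counts were changed by known sizes. Recovery in the real data need not be the same. For Catalpol against vehicle, with 19235 genes in the fit, the quasi-likelihood test recovered 12%, 76%, 100% and 100% of genes changed by 0.5, 1, 2 and 3 on the log2 scale. With batches added to the simulation, 1.88% of unchanged genes were called without a batch term and 0.0576% with one. The batch term also cost recovery, from 20% and 70% of genes changed by 0.5 and 1 to 0% and 36%. Catalpol lies in batch 3, which holds vehicle libraries, so this cost is not that of batches 2, 4 and 5, which hold none. As a background, 3 vehicle libraries drawn at random were compared with the other 7 in 32 draws, and the draw with the most calls had 1 gene. These draws mix the batches. Vehicle libraries parted by batch differed in 19 genes (batch 3 against 1), 439 (6 against 1) and 883 (6 against 3), although that parting was itself made from their counts, which favours differences. For chance results, the group labels of all libraries were dealt again at random 21 times, the real labels included.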

Results

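The series asked how single compounds of the herbal formula Samul-tang act on the ovaries of aged mice. Female Balb/c mice, 38 weeks old, were dosed by mouth with vehicle (water with 0.5% DMSO) or with 1 of 39 compounds at 5 mg/kg, 5 times a week for 4 weeks. They then received 5 IU of PMSG, a gonadotropin that drives follicle growth, and 48 h later 5 IU of hCG, which triggers ovulation. The left ovary was taken 14 to 16 h after hCG. Each compound group held 3 libraries and the vehicle group 10. The lowest total, 3.84 M counts, belonged to replicate 2 of Chlorogenic Acid, in which 6882 genes had a count against 21992 and 23192 in its group's other libraries. The next lowest held 9.67 M, and the median was 12.7 M. The SE of a compound's log2 fold change against vehicle had a median over genes of 0.263 in Catalpol.

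Besides their groups, the libraries differed by batch. In the order of the series the compound libraries fell into 6 consecutive runs with alike levels of pseudogenes, gene models, histone genes and small RNAs, called batches 1 to 6 here. Vehicle libraries, listed first in the series, were placed by their counts in the nearest run, which is not a record of how they were handled. By that placing they stood in batch 1 (4), batch 3 (3) and batch 6 (3), and batches 2, 4 and 5 had none. Vehicle libraries of a batch were thus picked for likeness to its compounds, which by itself favours few differences. Over genes outside those classes, the median correlation across genes between libraries of different compounds was 0.25 within a batch and -0.06 between batches (genes are not independent replicates). With no vehicle library in batches 2, 4 and 5, the batch and the compound cannot be told apart there against vehicle, and each is also set against the other compounds of its batch. Comparisons within a batch leave out replicate 2 of Chlorogenic Acid, while counts against all vehicle libraries keep it unless said otherwise.

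**Figure D1:**
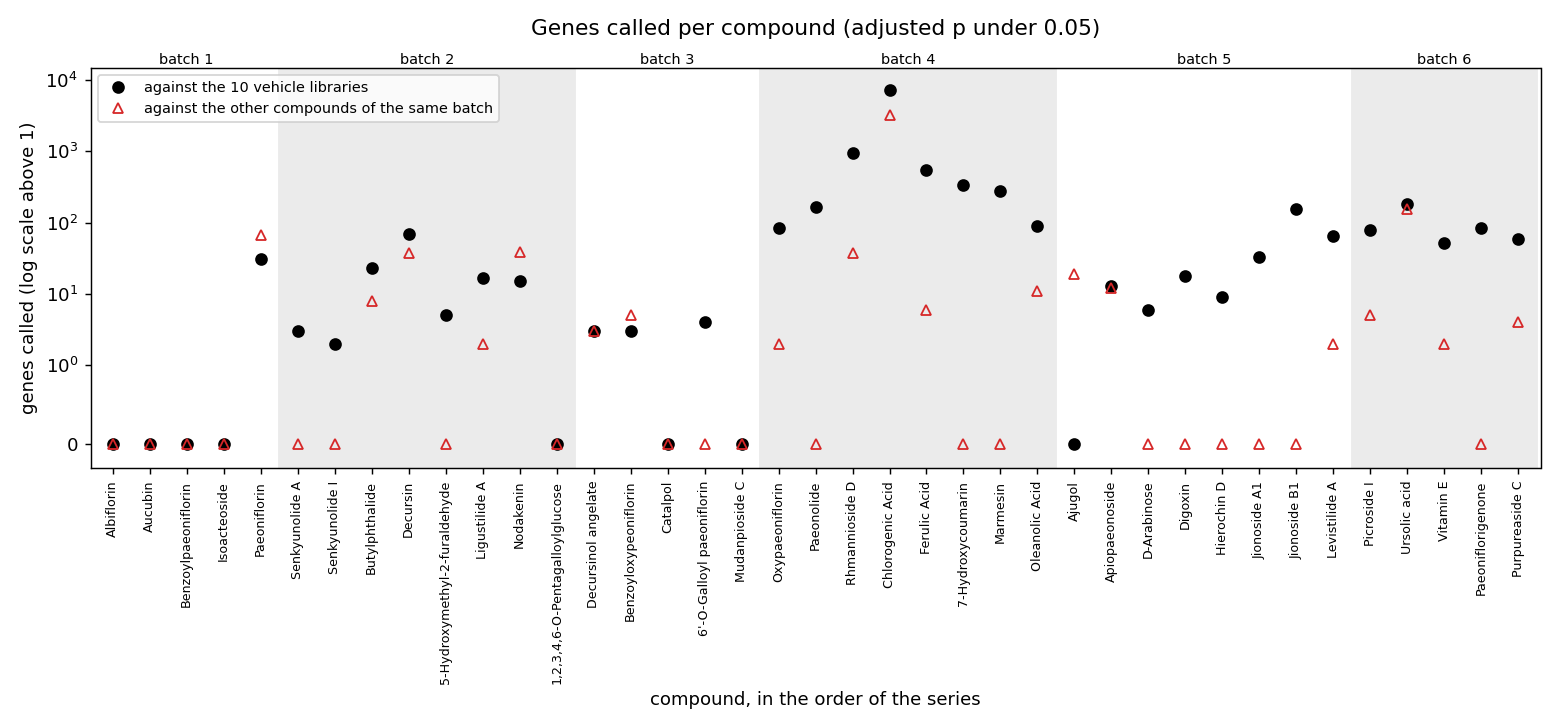
Genes called by edgeR (adjusted p under 0.05) for each compound, against all vehicle libraries and against the other compounds of its batch, on a log axis, with compounds in series order and shading marking the 6 batches. Oxypaeoniflorin, Decursinol angelate and Levistilide A, which lie across a border, are drawn in batches 4, 3 and 5; the 6 compounds with all libraries in batch 4, Chlorogenic Acid set aside, sum to 2364 calls against vehicle. Without replicate 2 of Chlorogenic Acid they sum to 12703 against vehicle and to 55 against the other compounds of the batch.

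The 2 genes called in most compounds, Tef and Dbp, belong to the output of the circadian clock. Tef (ENSMUSG00000022389), a clock output transcription factor, was called higher in 24 of 39 compounds, from 51.8 ± 6.88 CPM (SD, n = 10) in vehicle to 110.0 CPM in Levistilide A (log2 fold change 1.09 ± 0.14 (SE), adjusted p = 9.77e-08), and its fold change was above 0 in all 39. Dbp (ENSMUSG00000059824), of the same family, was called higher in 14 compounds and reached 86.3 CPM in Levistilide A against 11.3 ± 5.47 CPM in vehicle (log2 2.93 ± 0.37, adjusted p = 1.01e-07). The period gene Per3 (ENSMUSG00000028957) was called higher in 11 compounds, with its largest change in Butylphthalide (log2 1.46 ± 0.20, adjusted p = 1e-06). Arntl, which encodes the clock activator BMAL1 and runs in the opposite phase, was called lower in 5 compounds and fell by 1.28 ± 0.26 on the log2 scale in Levistilide A. Of 16 clock genes measured in the 38 compounds other than Chlorogenic Acid, 52 combinations of gene and compound were called higher and 4 lower (135 and 19 adjusted over the list alone). Camera called the clock list in 18 compounds with a preset correlation and in none with the estimated one, where the smallest adjusted p was 0.999. Without replicate 2 of Chlorogenic Acid the estimated correlation fell and the list was called in Senkyunolide A, Senkyunolide I, Butylphthalide, Decursin and Levistilide A (adjusted p = 0.00162 in the last), and Per3 was called in 26 compounds. Compared with the other compounds of the batch, Tef was called in 3 compounds, Dbp in 2 and Per3 in 3, and with a batch term in 5, 0 and 2.

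**Figure D2:**
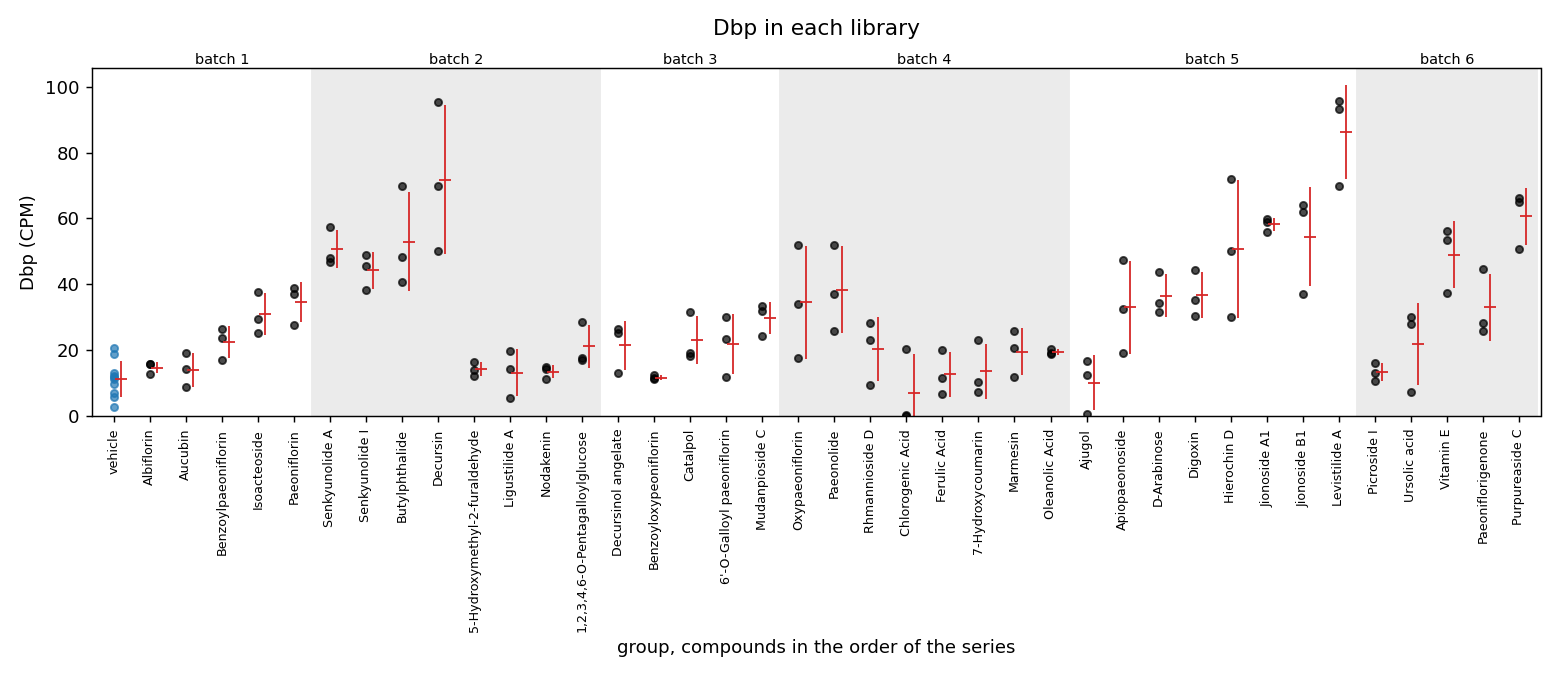
Dbp level (CPM, linear axis) in each library, with compounds in the order of the series and batches marked by shading; points are libraries, and red marks give mean ± SD. Vehicle libraries average 11.3 CPM, and the highest library is replicate 3 of Levistilide A at 95.6 CPM.

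Other genes that recurred across compounds were the chaperone genes Hspa1b and Hspa1a, called lower in 9 and 7 compounds. Hspa1b (ENSMUSG00000090877) stood at 22.8 ± 7.59 CPM in vehicle and at 4.33 CPM in Paeonolide. Smarca2, a chromatin remodelling ATPase, was called higher in 11 compounds, the small GTPase gene Rab24 in 9 and Cd2bp2 in 9. Lower calls recurred for the receptor gene Olfr1033 (10 compounds), the cell surface proteoglycan Sdc4 (10), the transcription factor Tead1 (9) and mt-Rnr2, the mitochondrial 16S rRNA (9). Banp was called lower in 9 and higher in 1, Chlorogenic Acid. In all, 11 genes were called in 10 or more compounds with both directions counted. Taken by direction, 4 were higher in 10 or more and 6 lower in 10 or more, where calls of independent lists of these sizes give 6.24e-15 genes higher and 3.2e-14 lower. All compounds share the vehicle libraries. In 4 simulations of unchanged compounds against them the most recurrent gene was called in at most 1 compound. No batch was simulated, so these cannot show how many genes a batch would make recur. Dealing the labels of all libraries again gave no gene in 10 or more compounds in 17 of 20 deals. The other 3 gave 6, 12 and 31, and in each of these replicate 2 of Chlorogenic Acid was among the vehicle libraries. With the vehicle libraries split, so that 20 compounds were set against 5 of them and 19 against the other 5, Tef was called in 15 compounds, Dbp in 7, Per3 in 4 and Hspa1b in 6, and 1 gene was called in 10 or more. With a batch term Olfr1033, Sdc4, Rab24, Tead1, mt-Rnr2 and Cd2bp2 were called in 0 compounds (by edgeR), Hspa1b and Smarca2 in 1 and Banp in 3. Against the other compounds of the batch Banp was called in 9 compounds, Hspa1b in 2, Olfr1033 in 1 and Smarca2, Sdc4, Rab24, Tead1, mt-Rnr2 and Cd2bp2 in 0 (by edgeR).

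Genes of hormone synthesis, hormone response and the oocyte differed from vehicle in few compounds. Star, which brings cholesterol into mitochondria and limits steroid synthesis, averaged 1646 ± 161 CPM (SD, n = 10) in vehicle, and its log2 fold changes ran from -0.51 (Nodakenin) to 0.84 (Levistilide A), none called (smallest adjusted p = 0.155). The smallest adjusted p in any compound was 0.0799 for Cyp11a1, the side chain cleavage enzyme, 0.277 for the LH receptor gene Lhcgr, 0.255 for the FSH receptor gene Fshr, 0.251 for the progesterone receptor gene Pgr and 0.166 for Zp3 of the oocyte coat. Hsd3b1, which makes progesterone, was called in Chlorogenic Acid (-1.09, adjusted p = 7.05e-07), as was Gdf9, an oocyte growth factor (0.91, adjusted p = 0.00209). Without the doubted replicate 2 of that group they stayed called, at -0.63 and 0.94. Ptgs2, the prostaglandin synthase that ovulation needs, was low in every group at this time, with 1.51 ± 1.08 CPM in vehicle. It was called lower in Rhmannioside D (log2 -3.51 ± 1.05) and in Chlorogenic Acid, where all 3 libraries had 0 counts and the level was at least 12.5-fold lower than in vehicle (3 counts over the group taken as the limit). Its mean over all compounds also lay below vehicle (log2 -1.91 ± 0.34, adjusted p = 6.43e-05). Cyp17a1, the androgen synthesis enzyme of theca cells, was called higher in Butylphthalide (log2 3.74, adjusted p = 0.0131) through replicate 3, at 508 CPM against 28.0 and 12.1. Without compound replicate 3 it was 0.55. Aromatase, Cyp19a1, was called higher in 7-Hydroxycoumarin at the limit of the test (log2 2.12, adjusted p = 0.0490), with 59.2 CPM in replicate 3 against 15.7 and 18.5. Amh, made by granulosa cells of small follicles, was below the filter, with at most 6 counts in a library. The edgeR test of any difference among compounds (all libraries fitted) cannot tell compound from batch. It called Cyp11a1 (adjusted p = 1.78e-07), Hsd3b1 (0.00126), Cyp17a1 (0.00172), Gdf9 (0.00838) and Zp3 (0.0284). Star, Cyp19a1, Lhcgr, Fshr, Pgr and Ptgs2 were not called. Against vehicle Cyp11a1 ran from log2 -0.46 (Picroside I, batch 6) to 0.50 (Marmesin, batch 4).

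**Figure D3:**
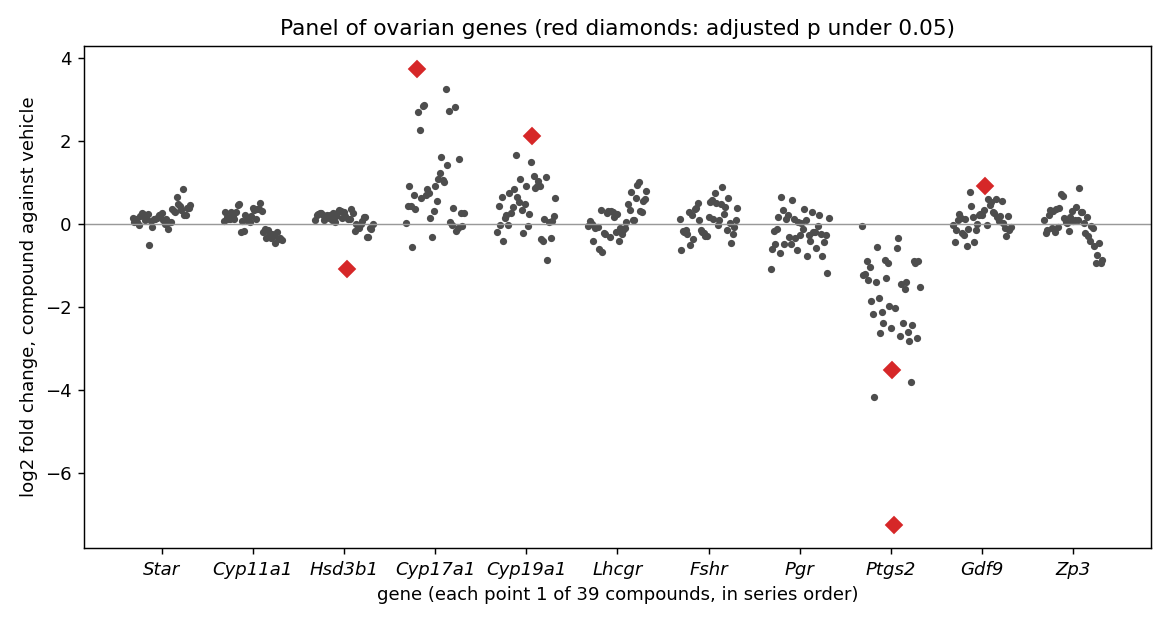
Log2 fold change against vehicle of the panel genes (11 tested) in each compound, one column of points per gene with called points marked. The lowest point of Ptgs2, Chlorogenic Acid with 0 counts in all libraries, is a fitted value that stands for a level at least 12.5-fold lower, and the points of Star lie between -0.51 and 0.84.

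In the fit of all libraries Chlorogenic Acid gave the most calls, 7207 genes (2459 higher and 4748 lower by edgeR, 2579 and 5282 by DESeq2), and its largest rises came from 1 library. In fits of the 2 compared groups alone it had 1114 calls, and 5 compounds had more, led by Rhmannioside D with 2916. Pigr (ENSMUSG00000026417), the polymeric immunoglobulin receptor, stood at 1345 CPM in replicate 2 against 9.17 and 10.0 in the others and 6.00 ± 1.75 CPM in vehicle (log2 fold change 6.23 ± 0.40 (SE), adjusted p = 8.29e-24). Bc1-ps1, Ccr4, Bco1, the hair cell gene Otof, the glycerol channel Aqp7, the muscle genes Klhl41 and Mylk4, Vmn1r218, Napsa and the blood cell factor Gata1 had the same form, with log2 fold changes from 5.39 to 7.85. Without replicate 2 of this group 0.66 was left for Pigr, and of these 11 genes Gata1 (2.34, adjusted p = 0.00266) and Vmn1r218 (2.01, adjusted p = 0.0129) stayed called. The named genes with the largest falls each stayed called without replicate 2. Adcyap1, which encodes a peptide that gonadotropin induces in follicles, had 3.31 ± 3.85 CPM (SD, n = 3) against 26.9 ± 8.64 CPM (SD, n = 10) in vehicle (log2 -2.73 ± 0.64, adjusted p = 0.000341). Pfn1, an actin binding protein, was at 9.07 against 58.4 CPM, the mitochondrial peptidase subunit Pmpcb at 14.5 against 93.2 CPM, and Idi1 of cholesterol synthesis at 19.1 against 118 CPM. Sdhd, Hacd2, Tap2, the Wnt receptor Fzd1, Echdc1, Olfr1033, Dram1 and Ly6d fell by 2.43 to 3.36 on the log2 scale. Lists with the most members called lower in this compound were cell cycle (20 of 28 lower), nuclear genes of the respiratory chain (13 of 29 lower), collagen and fibrosis enzymes (10 of 20 lower) and the mitochondrial genome (10 of 13 lower), each with a camera adjusted p of 0.999. Replicate 2 held 1.03% mitochondrial counts against 8.85% and 10.9% in the others, and without it these lists had 17, 11, 8 and 2 members lower, with 7 of the respiratory chain and 2 of the mitochondrial genome higher. Cytosolic ribosomal protein genes had a median log2 fold change of -0.14, a mean of 0.01 and a camera direction of up (adjusted p = 0.999). Of these 37 genes 6 were called higher and 9 lower, and without replicate 2 16 and 2. Without replicate 2 4977 genes were called, against the other compounds of the batch 3259, and with a batch term 32. Bco1 turned sign against the other compounds, and Klhl41 and Napsa with the batch term.

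Rhmannioside D differed from vehicle in 936 genes (332 higher and 604 lower by edgeR, 645 and 1369 by DESeq2). Ptgs2 fell, as above, and the stress chaperone Hspa1b fell to 4.76 ± 1.40 CPM (SD, n = 3) against 22.8 ± 7.59 CPM (SD, n = 10) in vehicle (log2 -2.26 ± 0.42, adjusted p = 0.000463). Idi1 was at 20.7 against 118 CPM (log2 -2.51 ± 0.55, adjusted p = 0.00303) and the fatty acid elongation gene Hacd2 at 6.70 against 35.9 CPM. Sdhd, a subunit of respiratory complex II, was at 1.17 against 18.4 CPM and the growth inhibitor gene Rerg at 2.19 against 15.5 CPM. Mrps28, Snhg6, Tap2, Lrrc57, Slc25a22, the splicing protein Snrpf and the centrosome gene Cntrob fell by 1.97 to 2.90 on the log2 scale. The largest rises were those of the ephrin receptor gene Ephb3 (13.9 ± 3.01 CPM (SD, n = 3) against 5.91 ± 1.26 CPM (SD, n = 10) in vehicle, log2 1.23 ± 0.27, adjusted p = 0.00277), Tmem98 (70.0 against 32.5 CPM) and the transcription factor Tox2 (125 against 59.8 CPM). Baiap3, Tef, Nat8f1, the secretory kinase Fam20c, the epithelial keratin Krt18, Osbpl5, the mitotic phosphatase Cdc25b, BC052040 and the cytokine receptor Csf2ra also rose, and the 12 log2 fold changes ran from 0.86 to 1.23. Of 18 genes of the ovulatory response 4 were called lower (6 adjusted over the list alone; camera adjusted p = 0.00326 with a preset correlation and 0.999 with the estimated one). Against the other compounds of batch 4 38 genes were called, among the named genes Tmem98 (log2 0.71, adjusted p = 0.000280) and BC052040 (0.66, 0.0337), and the sign of Mrps28, Tap2 and Snrpf turned with a batch term. With replicate 3 of every compound left out at once, written as without compound replicate 3 here, the count was 54, and without compound replicate 1 it was 490.

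Ferulic Acid differed from vehicle in 554 genes (261 higher and 293 lower by edgeR, 552 and 877 by DESeq2), with macrophage and fat cell transcripts among the largest rises. C1qb (ENSMUSG00000036905), a complement component made by macrophages, rose to 64.8 ± 7.36 CPM (SD, n = 3) against 27.7 ± 5.94 CPM (SD, n = 10) in vehicle (log2 fold change 1.23 ± 0.24 (SE), adjusted p = 0.000932). Lysozyme Lyz2 was at 349 against 153 CPM, the microglia and macrophage receptor Trem2 at 15.5 against 6.99 CPM and its adaptor Tyrobp at 23.4 against 10.8 CPM. The leukocyte antigen Cd52 and the chemokine Ccl21a rose by 1.26 and 1.19 on the log2 scale. Of 15 macrophage genes 7 were called higher (13 adjusted over the list alone), with a camera adjusted p of 1.48e-07 with the preset correlation and 0.999 with the estimated one. Cfd, the adipocyte protease adipsin, stood at 34.2, 99.0 and 53.4 CPM against 1.75 ± 2.50 CPM (SD, n = 10) in vehicle (log2 5.19 ± 1.04, adjusted p = 0.00182). In all, 4 of 10 adipose genes were called higher (7 adjusted over the list alone; camera adjusted p = 0.0905). Rises also included Rpl23a-ps3, the stress gene Nupr1, the cysteine dioxygenase Cdo1, Man1c1 and AC117239.2. The largest falls included those of Sdhd, Snord89, Snrpf, the growth regulator Myc (1.92 against 6.65 CPM), AA474408, Rerg, Mterf3, Cdv3-ps, the linker histone Hist1h1e (22.4 against 60.2 CPM), the mitochondrial 12S rRNA mt-Rnr1 and Spcs3, which fell by 1.28 to 2.83 on the log2 scale. With the other compounds of the batch as the reference 6 genes were called. Cfd was kept (log2 5.23, adjusted p = 0.00109), while C1qb was at 0.54 (adjusted p = 0.453) and Sdhd, Snrpf and Rerg turned sign with a batch term. Without compound replicate 1 the count was 41, and without compound replicate 3 it was 72.

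The remaining compounds of batch 4 shared some of their leading genes. mt-Rnr2 stood at 12988 against 28403 CPM in 7-Hydroxycoumarin (log2 -1.13 ± 0.17, adjusted p = 8.55e-06) and at 14497 CPM in Marmesin (log2 -0.97 ± 0.16, adjusted p = 0.000375), and Btbd7, a regulator of epithelial branching, fell in both (-0.78 and -0.63). Fkbp4, a co-chaperone of steroid receptors, rose in 7-Hydroxycoumarin (298 ± 90.7 CPM (SD, n = 3) against 168 ± 30.9 CPM (SD, n = 10) in vehicle), and the co-chaperone Dnajb2 rose in Marmesin (log2 0.94 ± 0.16). In Oleanolic Acid the complex I subunit Ndufv3 rose by 0.64 and Emc1 by 0.57, and the poly(A) binding protein Pabpc1 was at 889 against 1611 CPM. The adaptor gene Crk fell in Paeonolide (-0.73 ± 0.13), where Tef and Per3 rose by 0.99 and 1.18, and in Oxypaeoniflorin (-0.74), where Jup, the junction protein plakoglobin, rose to 95.6 against 35.9 CPM (log2 1.41 ± 0.22, adjusted p = 0.000171) and Tef by 0.77. Calls numbered 343 in 7-Hydroxycoumarin (166 higher and 177 lower by edgeR, 421 and 621 by DESeq2), 276 in Marmesin (139 higher and 137 lower by edgeR, 343 and 506 by DESeq2), 166 in Paeonolide (85 higher and 81 lower by edgeR, 338 and 499 by DESeq2), 89 in Oleanolic Acid (45 higher and 44 lower by edgeR, 171 and 348 by DESeq2) and 83 in Oxypaeoniflorin (39 higher and 44 lower by edgeR, 146 and 246 by DESeq2). Cytosolic ribosomal protein genes were called higher in 5 of 37 in both 7-Hydroxycoumarin and Marmesin, and Rps20 in 8 compounds (camera adjusted p = 0.999 with the estimated correlation). Counts against the other compounds of the batch were 0 for 7-Hydroxycoumarin, Marmesin and Paeonolide, 11 for Oleanolic Acid and 2 for Oxypaeoniflorin (counts of 0 by edgeR, with no DESeq2 run of this setting), where Emc1 turned sign in Oleanolic Acid. Without compound replicate 3 the counts were 24, 1, 0, 13 and 1 in the order above.

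In batch 1, transcripts of the oviduct, the duct next to the ovary, were higher in 2 of the 3 Paeoniflorin libraries. Ovgp1 (ENSMUSG00000074340), an oviduct secretory glycoprotein, stood at 60.9, 0.918 and 19.4 CPM in the 3 libraries against 1.53 ± 0.731 CPM (SD, n = 10) in vehicle (log2 fold change 4.14 ± 0.37, adjusted p = 8.99e-15). The cilia regulator Foxj1 stood at 17.5 and 7.29 CPM in replicates 1 and 3, and Dynlrb2, Sec14l3 and Ccdc153 of ciliated cells were also called. Of 11 oviduct genes 5 were called higher (10 adjusted over the list alone), and this was the single call among all combinations of list and compound with the estimated correlation (camera adjusted p = 1.43e-07). It was lost without compound replicate 1, where the single call was adipose tissue in Ferulic Acid (adjusted p = 0.0376). Tef rose in all 3 libraries (log2 0.60 ± 0.14, adjusted p = 0.0388). Paeoniflorin had 31 calls (31 higher and 0 lower by edgeR, 26 and 11 by DESeq2), 19 against the vehicle libraries of its batch, and 1 without compound replicate 1. No gene was called by edgeR in Albiflorin (273 at an unadjusted p under 0.05, 3 by DESeq2), Aucubin (422 and 3), Benzoylpaeoniflorin (437 and 10) and Isoacteoside (565 and 3).

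In batch 2 Dbp was among the leading calls of Decursin, Butylphthalide, Senkyunolide A and Senkyunolide I. Decursin, a coumarin, had 70 calls (46 higher and 24 lower by edgeR, 237 and 247 by DESeq2), with Dbp at 71.8 ± 22.6 CPM (SD, n = 3) against 11.3 ± 5.47 CPM (SD, n = 10) in vehicle (log2 2.66 ± 0.38, adjusted p = 3.28e-06), Tef at 1.03 and the sterol isomerase relative Ebpl at 0.57. Butylphthalide had 23 (15 higher and 8 lower by edgeR, 61 and 88 by DESeq2), with Tef at 1.05 and Dbp at 2.22. Senkyunolide A had 3 (3 higher and 0 lower by edgeR, 7 and 8 by DESeq2), which were Tef (0.88), Dbp (2.16) and Cd2bp2 (0.60), and Senkyunolide I 2 (2 higher and 0 lower by edgeR, 6 and 10 by DESeq2), Dbp (1.96) and Scarna2 (2.01). In Nodakenin the fatty acid carrier Fabp3 was higher through replicate 1, at 77.3 CPM against 8.72 and 6.45 (log2 2.31 ± 0.46, adjusted p = 0.0205), as was the germ cell gene Tdrd5 (41.8 against 7.64 and 7.06 CPM, log2 1.57), and Tef rose by 0.68 among 15 calls (11 higher and 4 lower by edgeR, 22 and 16 by DESeq2). Ligustilide A had 17 calls (10 higher and 7 lower by edgeR, 109 and 189 by DESeq2), led by lower mt-Rnr2 (-0.86), higher Nudt16l1 (0.49) and lower Morf4l1-ps1 (29.2 CPM). 5-Hydroxymethyl-2-furaldehyde had 5 (2 higher and 3 lower by edgeR, 37 and 143 by DESeq2), the autophagy gene Map1lc3a (0.70), the Golgi adaptor Gga1 (0.53), Morf4l1-ps1 (-0.98), Sept7 (-0.52) and Zfp142 (-1.57). 1,2,3,4,6-O-Pentagalloylglucose had none by edgeR (1504 at an unadjusted p under 0.05 and 69 by DESeq2). Without compound replicate 3 the counts were 19 for Decursin, 25 for Nodakenin and 0 for Butylphthalide and Ligustilide A (by edgeR). Without compound replicate 1 they were 3 for Decursin, 0 for Nodakenin, 13 for Butylphthalide and 6 for Ligustilide A. Without compound replicate 2 they were 670, 314, 281 and 300 in that order. Set against the other compounds of the batch, Decursin had 38 calls and Nodakenin 39. The counts against vehicle with all libraries, and those without compound replicate 1 or 3, share a fit with replicate 2 of Chlorogenic Acid. Those without compound replicate 2 and those against the other compounds come from fits that leave it out. With that library alone left out, counts against vehicle were 1228 for Decursin, 460 for Butylphthalide, 26 for Senkyunolide A and 37 for Senkyunolide I. Nodakenin then had 233, Ligustilide A 1031, 5-Hydroxymethyl-2-furaldehyde 607 and 1,2,3,4,6-O-Pentagalloylglucose 215.

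In batch 3 few genes were called. Decursinol angelate had 3 calls (1 higher and 2 lower by edgeR, 7 and 12 by DESeq2), lower Banp (-0.68 ± 0.12), lower Dnajb1, a heat shock co-chaperone (31.3 ± 4.32 CPM (SD, n = 3) against 55.4 ± 7.11 CPM (SD, n = 10) in vehicle), and higher Neat1, a nuclear long noncoding RNA (1083 against 651 CPM). Benzoyloxypeoniflorin had 3 (3 higher and 0 lower by edgeR, 3 and 6 by DESeq2), the adipocyte genes Cfd, Adipoq and Retn, all highest in replicate 1, with Adipoq at 34.8, 2.54 and 0, Retn at 19.5, 2.30 and 0.585 and Cfd at 169.6, 7.55 and 0.251 CPM in replicates 1, 2 and 3. Without compound replicate 1 the count was 0. 6'-O-Galloyl paeoniflorin had 4 (4 higher and 0 lower by edgeR, 11 and 6 by DESeq2), pseudogenes or gene models, of which Rps19-ps6 was at 11.9 against 4.42 CPM and the others, Rpl39-ps, Gm10288 and Gm6368, had log2 fold changes of 1.98, 1.35 and 1.67. Catalpol (511 genes at an unadjusted p under 0.05, 14 by DESeq2) and Mudanpioside C (648 and 16) had none by edgeR. Against the vehicle libraries of the batch Decursinol angelate had 85 calls and 6'-O-Galloyl paeoniflorin 36.

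In batch 5, Dbp and Tef led in Levistilide A (values above; 66 calls, 25 higher and 41 lower by edgeR, 73 and 182 by DESeq2), where Banp fell to 58.0 ± 4.33 CPM (SD, n = 3) against 99.6 ± 6.92 CPM (SD, n = 10) in vehicle. They also led in Jionoside A1 (Dbp 2.36, Tef 0.79, Banp -0.66; 33 calls, 11 higher and 22 lower by edgeR, 24 and 104 by DESeq2) and in Jionoside B1 (Tef 0.91, Dbp 2.26; 156 calls, 75 higher and 81 lower by edgeR, 145 and 322 by DESeq2), where the centrosome gene Cdk5rap2 rose to 118 ± 41.8 CPM (SD, n = 3) against 53.2 ± 5.35 CPM (SD, n = 10) in vehicle (log2 1.16 ± 0.20, adjusted p = 0.000808). Hierochin D had higher Dbp (2.16) and Tef (0.70) and lower Hspa1b (5.89 against 22.8 CPM; 9 calls, 3 higher and 6 lower by edgeR, 13 and 56 by DESeq2). D-Arabinose had higher Tef (0.77), Cdk5rap2 (1.07) and Tbcel (0.56; 6 calls, 4 higher and 2 lower by edgeR, 20 and 68 by DESeq2). Digoxin, an inhibitor of the sodium pump, had higher Smarca2 (591 ± 59.4 CPM (SD, n = 3) against 412 ± 37.8 CPM (SD, n = 10) in vehicle, log2 0.52 ± 0.09, adjusted p = 0.00483), Mansc4 (1.16) and the apoptosis regulator Pawr (0.72; 18 calls, 8 higher and 10 lower by edgeR, 58 and 173 by DESeq2). Apiopaeonoside had higher Mansc4 (1.20) and Smarca2 (0.43) and lower Arntl (9.52 against 21.1 CPM; 13 calls, 3 higher and 10 lower by edgeR, 27 and 182 by DESeq2). Ajugol had none by edgeR (1366 at an unadjusted p under 0.05 and 56 by DESeq2). Cdk5rap2 was highest in replicate 1 of D-Arabinose (162 CPM against 94.0 and 79.9) and in replicate 2 of Jionoside B1 (163 against 113 and 79.4). Against the other compounds of the batch Apiopaeonoside had 12 calls, Ajugol 19, Levistilide A 2 and the others 0 by edgeR. These come from a fit without replicate 2 of Chlorogenic Acid. Against vehicle without that library, Apiopaeonoside had 409 calls, Ajugol 158 and Levistilide A 522. Jionoside B1 had 40 calls without compound replicate 2 and Levistilide A 9 without compound replicate 3.

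In batch 6 Ursolic acid carried transcripts of the lung in 1 library. Ager (ENSMUSG00000015452), a receptor that is abundant in alveolar cells, stood at 478 CPM in replicate 2 against 2.65 and 2.64 in the others and 2.58 ± 0.984 CPM in vehicle (log2 5.98 ± 0.43, adjusted p = 4.74e-20). Scgb1a1, the secretory protein of airway club cells, was at 3127 CPM there against 0.779 and 0.660. The epithelial cadherin Cdh1 was at 40.6 CPM against 4.28 and 6.23, and Limch1 at 118 against 28.2 and 19.7. Ursolic acid had 183 calls (121 higher and 62 lower by edgeR, 160 and 207 by DESeq2), and 1 without compound replicate 2. In Purpureaside C the melanin enzyme Dct was higher, through replicate 1 at 42.2 CPM against 4.81 and 3.21, along with Dbp (2.42) and Tef (0.78; 59 calls, 19 higher and 40 lower by edgeR, 43 and 163 by DESeq2). Picroside I had higher Pigt, a subunit of the enzyme that attaches membrane anchors (60.1 ± 16.5 CPM (SD, n = 3) against 23.9 ± 7.82 CPM (SD, n = 10) in vehicle, log2 1.33 ± 0.25, adjusted p = 0.00157), and lower Sdsl (-0.98) and Rps10-ps1 (-1.55; 78 calls, 27 higher and 51 lower by edgeR, 69 and 219 by DESeq2). Vitamin E had higher Dbp (2.11) and the acyl-CoA thioesterase Acot2 (0.95) and lower the coatomer subunit Copg1 (-0.61; 52 calls, 16 higher and 36 lower by edgeR, 51 and 193 by DESeq2). Paeoniflorigenone had lower Rpl10a-ps1 (-1.80), Tmem258 (-0.74 ± 0.13) and Nt5dc2 (-1.56; 85 calls, 16 higher and 69 lower by edgeR, 46 and 272 by DESeq2). Against the vehicle libraries of the batch the counts were 150 for Ursolic acid, 46 for Picroside I, 15 for Paeoniflorigenone, 11 for Purpureaside C and 7 for Vitamin E. That fit leaves out replicate 2 of Chlorogenic Acid. Without that library they had 881, 748, 619, 498 and 549 against all vehicle libraries, in the same order. Without compound replicate 1 the last 4 had 1, 2, 1 and 3.

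**Figure D4:**
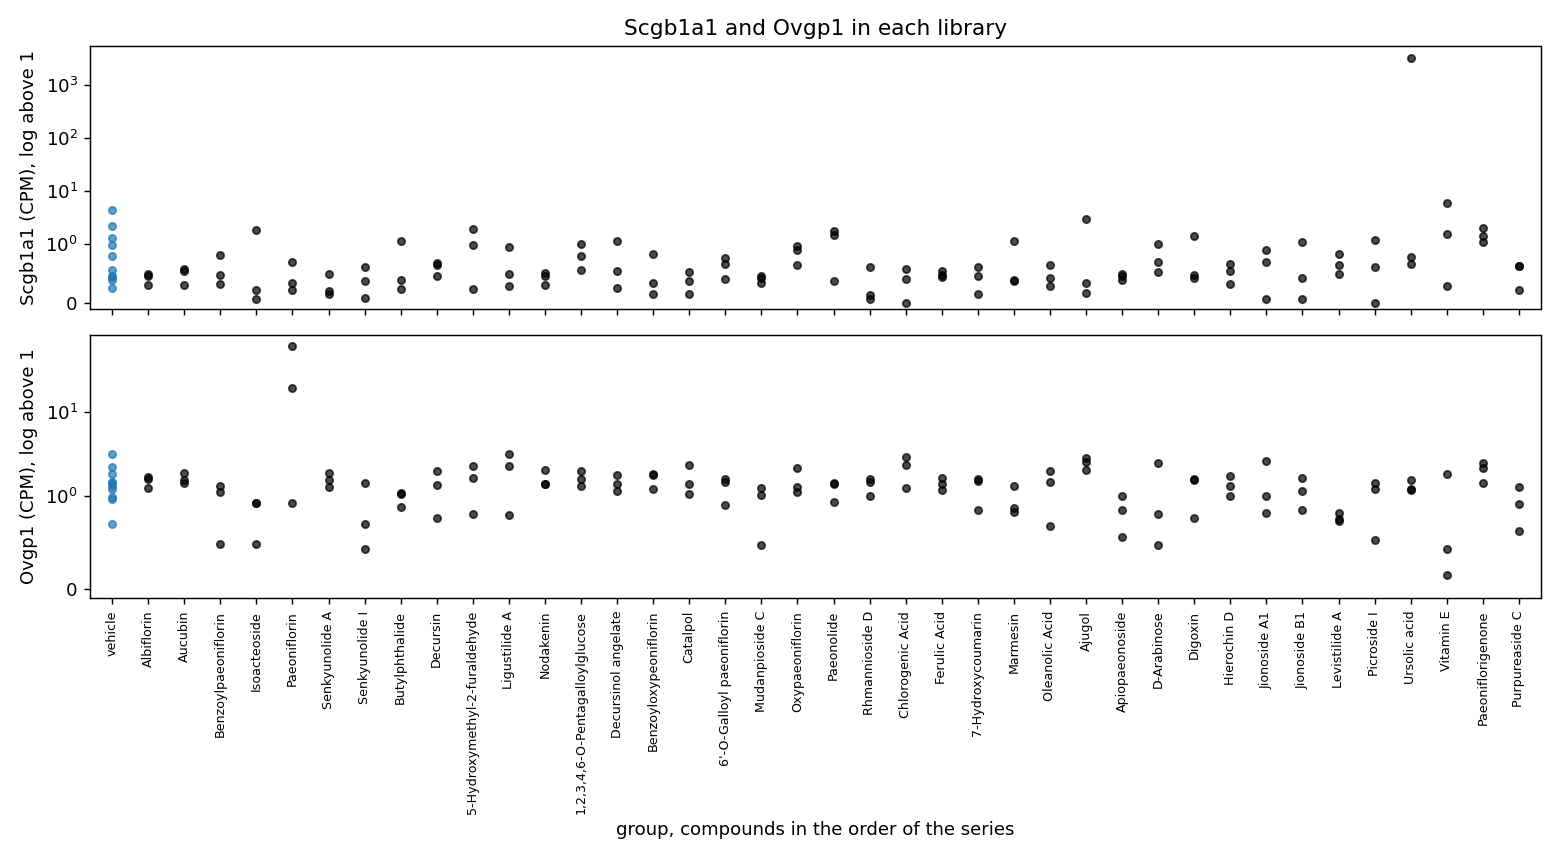
Levels in CPM of the airway gene Scgb1a1 and the oviduct gene Ovgp1 in each library, on log axes, with series order along the x axis. Replicate 2 of Ursolic acid reaches 3127 CPM of Scgb1a1, and replicates 1 and 3 of Paeoniflorin reach 60.9 and 19.4 CPM of Ovgp1.

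Taken over all compounds, Tef had the smallest p of the contrast between the mean of the compounds and vehicle (log2 0.62 ± 0.08, adjusted p = 4.34e-09; compound means above the vehicle mean in 39 of 39). Per3 (0.64) and Rab24 (0.27) were higher, and Bzw1, a translation regulator (-0.42), Frmd5 (-0.33), Olfr1033 (-0.96), Hspa1b (-0.94), Tmem71 (-0.81), the kinase Prkg2 (-0.99) and Tead1 (-0.25) were lower. Prkg2, a cGMP-dependent kinase of granulosa cells, averaged 9.97 ± 3.35 CPM in vehicle and 5.23 CPM over the compounds, below vehicle in 39 of them. The contrast called 341 genes (50 higher and 291 lower by edgeR, 112 and 333 by DESeq2). It called 4126 with no filter on low counts, 13 with a replicate block, 213 to 1381 over the leave-one-out settings and 1 with a batch term. With the batch term it still covers all 39 compounds. Those of batches 2, 4 and 5 are then linked to vehicle only through Decursinol angelate, Oxypaeoniflorin and Levistilide A, whose libraries lie in 2 batches. The test of any difference among compounds, which leaves vehicle out, called 4873 genes, 8829 without replicate 2 of Chlorogenic Acid and 264 with a batch term. Its 10 leading genes were Scgb1a1 and Ager, highest in Ursolic acid, and Kcna2, Trim12c, Pigr, Ptpn7, Akap5, Lrrc17, Trim8 and Elp6, highest in Chlorogenic Acid, where Pigr was high in replicate 2 as above. With 1 adjustment over all compounds 7965 combinations of gene and compound were called, and 31 of 39 compounds had a call of their own by edgeR (39 by DESeq2). Without replicate 2 of Chlorogenic Acid 24833 combinations in 36 compounds were called, and with a batch term 114 in 16. Leaving out that library raised the sums of calls over compounds wholly in 1 batch, Chlorogenic Acid aside. They went from 31 to 74 in batch 1, 135 to 3837 in batch 2 and 7 to 78 in batch 3. In batches 4, 5 and 6 they went from 2364 to 12703, 235 to 2938 and 457 to 3295.

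Structurally related compounds, given at the same dose and time, were set against each other. Ovgp1 was lower in each of 4 relatives than in Paeoniflorin, through replicates 1 and 3 of Paeoniflorin. The log2 difference was -4.16 ± 0.58 for its isomer Albiflorin, -4.15 for Oxypaeoniflorin (an added hydroxyl on the benzoyl ring), -4.78 for Benzoylpaeoniflorin (an added benzoyl ester) and -4.36 for 6'-O-Galloyl paeoniflorin (an added galloyl ester). Without compound replicate 1 these pairs had 0 calls by edgeR. This was the 1 gene called for Albiflorin (0 higher and 1 lower by edgeR, 6 and 5 by DESeq2) and for Benzoylpaeoniflorin (0 higher and 1 lower by edgeR, 6 and 10 by DESeq2). Oxypaeoniflorin also had more Jup (95.6 ± 24.6 CPM (SD, n = 3) against 32.4 ± 0.187 CPM (SD, n = 3) in Paeoniflorin, log2 1.56 ± 0.31, adjusted p = 0.0150) and less of the gene model Gm12101 (-4.78) among 3 calls, and 6'-O-Galloyl paeoniflorin more Rps13-ps2 (2.34) among 7 (2 higher and 5 lower by edgeR, 12 and 10 by DESeq2). Paeoniflorin lies in batch 1, Oxypaeoniflorin in batches 3 and 4 and 6'-O-Galloyl paeoniflorin in batch 3, and with a batch term these 2 pairs had 0 and 2 calls (by edgeR). Ursolic acid and Oleanolic Acid, which differ in the place of 1 ring methyl group, differed in 338 genes (138 higher and 200 lower by edgeR, 341 and 408 by DESeq2), led by Scgb1a1 (11.14), Ager (6.13) and the centriole gene Cep295 (3.66), all through replicate 2 of Ursolic acid. Without compound replicate 1 the count was 49, and without compound replicate 2 589 genes were called and Cep295 was at -0.00216. Apiopaeonoside and Paeonolide, paeonol glycosides with different terminal pentoses, differed in 213 genes (97 higher and 116 lower by edgeR, 323 and 357 by DESeq2), with less Map1lc3a (119 ± 8.15 CPM (SD, n = 3) against 252 ± 23.7 CPM (SD, n = 3) in Paeonolide, log2 -1.09 ± 0.19, adjusted p = 0.000784) and more Btbd7 (0.73) and Crk (0.85) in Apiopaeonoside. Picroside I, which carries a cinnamoyl ester that Catalpol lacks, differed from it in 179 genes (50 higher and 129 lower by edgeR, 114 and 269 by DESeq2), led by the ribosomal pseudogenes Rps10-ps1 (-2.23) and Rpl31-ps8 (-2.60) and by Rpl37rt (-1.42). Without compound replicate 1 the pairs of Apiopaeonoside and of Picroside I had 0 and 13 calls, and without compound replicate 3 4 and 25. Each of these last 3 pairs lies in 2 batches, and with a batch term 0, 0 and 7 genes were called, in the order given, and Map1lc3a turned sign.

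For 3 pairs edgeR called no gene in the fit of all libraries. Decursinol angelate and Decursin, isomeric esters, had 1588 genes at an unadjusted p under 0.05 and 136 by DESeq2. Catalpol and Aucubin, an epoxide against a double bond, had 460 and 6, and Senkyunolide A and Butylphthalide, a partly hydrogenated against an aromatic ring, had 572 and 7. Without replicate 2 of Chlorogenic Acid, a library of none of these groups, edgeR called 394 genes between Decursinol angelate and Decursin. It then called 0 between Catalpol and Aucubin and 0 between Senkyunolide A and Butylphthalide. These pairs are not shown to act alike, since the 95% interval of a gene's difference extended 0.50 on each side in the median gene. For Star the interval ran from -0.83 to 0.51 between Decursinol angelate and Decursin, from -0.61 to 0.74 between Catalpol and Aucubin, and from -0.72 to 0.63 between Senkyunolide A and Butylphthalide. Cyp17a1 had the largest panel difference of the last pair (-3.05, interval -5.33 to -0.78, adjusted p = 1.00). No panel gene was called in any of the 10 pairs.

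Over the 38 compounds other than Chlorogenic Acid, the fixed list with the most calls was that of the clock, given above, followed by cytosolic ribosomal proteins and heat shock response. Counts here are combinations of gene and compound called higher and lower, with those adjusted over the list alone in parentheses. Steroidogenesis had 2 and 0 (21 and 3), cholesterol synthesis and uptake 0 and 3 (1 and 5) and response to the ovulatory gonadotropin surge 1 and 6 (4 and 51). Granulosa cells of growing follicles had 2 and 0 (16 and 0), cumulus cells and extracellular matrix of the cumulus 4 and 3 (7 and 32) and theca and interstitial steroid cells 4 and 0 (28 and 0). Corpus luteum had 0 and 1 (9 and 2), oocyte 0 and 0 (0 and 1) and surface epithelium 2 and 1 (8 and 15). Fibroblast and stroma had 4 and 0 (7 and 7), collagen and fibrosis enzymes 0 and 1 (1 and 7) and smooth muscle 1 and 0 (5 and 9). Endothelium had 3 and 0 (8 and 1), macrophage 7 and 0 (22 and 4) and B and T lymphocytes 1 and 0 (2 and 1). Neutrophil had 1 and 0 (2 and 4) and red blood cells 1 and 0 (8 and 3). Oviduct had 9 and 0 (24 and 2) and adipose tissue 7 and 0 (27 and 2). Among the oviduct calls, Tppp3, Wfdc2 and Sec14l3 were called in Ursolic acid, whose replicate 2 held lung transcripts. Wfdc2 and Tppp3 were highest in that library, at 73.6 and 31.7 CPM. Heat shock response had 3 and 19 (15 and 47), unfolded protein and integrated stress response 4 and 0 (12 and 8) and antioxidant and Nrf2 targets 1 and 1 (5 and 6). Immediate early genes had 1 and 3 (6 and 15), inflammatory cytokines and chemokines 1 and 4 (2 and 13) and interferon response 6 and 1 (21 and 2). Senescence and cell cycle arrest had 0 and 0 (1 and 14) and aryl hydrocarbon and xenobiotic response 1 and 1 (5 and 7). Cell cycle had 2 and 6 (2 and 22), cytosolic ribosomal proteins 24 and 1 (63 and 6) and mitochondrial respiratory chain (nuclear genes) 8 and 2 (20 and 5). Mitochondrial genome had 0 and 10 (12 and 20), hypoxia and glycolysis 1 and 1 (3 and 26) and lipid storage and fatty acid use 6 and 4 (12 and 7).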

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

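The deals of the group labels and every test of an explanation in this part were chosen only after the results they bear on had been seen; the rule by which single vehicle libraries are listed was set before.

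Some vehicle libraries lay far from the other 9 for a gene named in the report. Lhcgr, the LH receptor gene, stood at 642 CPM in vehicle replicate 8 (next highest 371), and Pgr at 4.92 CPM in vehicle replicate 6 (3.22). The clock gene Tef was lowest in vehicle replicate 5 at 35.7 CPM (next lowest 49.3). In vehicle replicate 6 Osbpl5 was at 27.6 CPM (20.5), Nt5dc2 at 45.0 (29.3), adipsin Cfd at 8.14 (3.83) and, at the low end, Pfn1 at 24.8. Rpl23a-ps3 stood at 60.4 CPM in vehicle replicate 4 (42.6), the macrophage gene Trem2 at 11.7 in vehicle replicate 7 (7.93) and Scgb1a1 at 4.47 in vehicle replicate 8 (2.24). In each the gap to the nearest library, divided by the range, exceeded Dixon's 95% critical value for 10 samples. These are 10 of 138 measures, and chance lists about 1 in 20. Some genes lay below the filter and so were left out of the main test. Among these the surfactant gene Sftpa1 stood at 158 CPM and the cytochrome gene Cyp2b10 at 35.6 CPM in replicate 2 of Ursolic acid. A vehicle library held at most 0.328 and 0.0657 CPM of them.

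The compounds of batch 4 had most of the calls against vehicle. Over 2364 calls in Paeonolide, Rhmannioside D, Ferulic Acid, 7-Hydroxycoumarin, Marmesin and Oleanolic Acid, the median change was 0.73 on the log2 scale against vehicle and 0.21 against the other compounds of the batch, and 24 calls were kept. The median share left was 0.291, from 0.152 in Paeonolide to 0.385 in Rhmannioside D, as a library batch would give. An effect that the compounds of the batch share would give the same, and these explanations cannot be told apart, since 0 vehicle libraries were placed in batch 4. Chlorogenic Acid, with its doubted replicate 2, is not part of this set. The genes of the set were picked by their change against vehicle, which by itself lowers the share left. The change against vehicle comes from a fit with that replicate, and the other from a fit without it. With it left out of both, the same compounds had 12703 calls against vehicle and 55 against the other compounds.

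Replicate 2 of Ursolic acid held transcripts of the lung. Of 12 lung markers 9 had their highest level of all libraries there, the exceptions being Cldn18, Napsa and Cbr2, as RNA from another tissue would give. An effect of the compound in each animal would raise Scgb1a1 in all 3 libraries of the group, and it lay above the highest vehicle library in 1, which argues against that explanation. How such RNA could have come into the library was not tested.

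The clock genes Tef, Dbp and Per3 were called higher than in vehicle in many compounds, while camera called the clock list in 0 compounds with the estimated correlation (smallest adjusted p = 0.999). That result turned on 1 library. Without replicate 2 of Chlorogenic Acid camera called the list higher in Senkyunolide A, Senkyunolide I, Butylphthalide, Decursin and Levistilide A. A score of 9 clock genes counted up and 3 counted down was correlated between neighbouring compounds of the series order within batches (r = 0.369, one-sided permutation p = 0.000770; rho = 0.491, permutation p = 6e-05; 33 pairs; r = 0.386 without the 2 farthest pairs), as an order of handling such as the hour of removal would give. A share of 0.686 of the score's spread within batches lay between compounds, where permuted libraries gave a median of 32.5% (permutation p = 0.000100, the smallest possible). Library batch cannot be told apart as the whole cause, since this share was taken over compound libraries alone. Libraries of a compound also stand side by side, so finer batches would give the same share and the same likeness of neighbours. Vehicle libraries scored -0.654 ± 0.266 (SD, n = 10), below the mean of each compound, the lowest being Ajugol at -0.649. Against vehicle of batch 3 its compounds as a set had Tef at 0.60 ± 0.11 and Nr1d2 at 0.71 ± 0.14 (edgeR adjusted p = 0.00863 and 0.00995). In batch 1 the 2 genes were at 0.40 ± 0.10 and 0.48 ± 0.12 (both 0.353). An effect of the compounds themselves cannot be told apart from the order of handling, since 0 compounds stand at 2 separate places of the order. The hours of removal are not given in the sources used here.

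Against chance, the group labels of all libraries were dealt 21 times, the real labels included, and the values in parentheses are the real result and the highest of the other deals. No other deal gave as many in Oxypaeoniflorin (83, 5), Paeonolide (166, 61), Rhmannioside D (936, 50), Chlorogenic Acid (7207, 73), 7-Hydroxycoumarin (343, 7), Oleanolic Acid (89, 55), Jionoside A1 (33, 2) and Picroside I (78, 1). The same held for Apiopaeonoside against Paeonolide (213, 14), any difference among compounds (4873, 949), combinations with 1 adjustment (7965, 1683) and compounds with a call (31, 21). Each stood first of 21 taken alone, the smallest share these deals can give. Among this many results some come first by chance, so this rank does not exclude chance for a single result. For each compound listed, 3 deals put replicate 2 of Chlorogenic Acid into a group compared, vehicle included. Without those the deals left are too few for a share under 0.05. The deals also break up the batches, so they do not tell a compound from its batch. Replicate 2 of Chlorogenic Acid stayed out of its own group in the other deals shown for it, and the 17 deals that put it in a compound group gave that group 1963 to 4056 genes, against at most 101 in any other, which points to a structure of that library. Chance is also not excluded where other deals gave as many. In 2 of 21 deals this was so for Paeoniflorin (31, 4056), Senkyunolide A (3, 7), Butylphthalide (23, 51), Ligustilide A (17, 3813) and Ferulic Acid (554, 2149). The same number held for Hierochin D (9, 51), Jionoside B1 (156, 2507), Levistilide A (66, 75), Ursolic acid (183, 2737) and Paeoniflorigenone (85, 100). The same number held for Purpureaside C (59, 3958), Ursolic acid against Oleanolic Acid (338, 1473), Oxypaeoniflorin against Paeoniflorin (3, 1937), 6'-O-Galloyl paeoniflorin against Paeoniflorin (7, 2811) and Picroside I against Catalpol (179, 1848). In 3 of 21 deals this was so for Senkyunolide I (2, 114), Decursin (70, 93), Nodakenin (15, 45), Marmesin (276, 3315) and Apiopaeonoside (13, 143). In 4 of 21 deals this was so for Benzoyloxypeoniflorin (3, 3568), 6'-O-Galloyl paeoniflorin (4, 99), D-Arabinose (6, 48), Digoxin (18, 50) and Vitamin E (52, 1963). The same number held for the mean of the compounds (341, 1306). In 5 of 21 deals this was so for 5-Hydroxymethyl-2-furaldehyde (5, 375), Decursinol angelate (3, 3065) and Albiflorin against Paeoniflorin (1, 2124). In 6 of 21 deals this was so for combinations of list and compound (1, 2). In 7 of 21 deals this was so for Benzoylpaeoniflorin against Paeoniflorin (1, 1788). For compounds and pairs, each highest value above 101 comes from a deal that put replicate 2 of Chlorogenic Acid into a group compared, vehicle included. With such deals set aside, the highest was below the real count in these results, at 1 in Paeoniflorin, 1 in Butylphthalide, 1 in Decursin, 11 in Ligustilide A, 2 in Benzoyloxypeoniflorin, 13 in Ferulic Acid, 55 in Marmesin, 17 in Jionoside B1 and 54 in Levistilide A. It was 3 in Ursolic acid, 1 in Vitamin E, 2 in Paeoniflorigenone, 8 in Purpureaside C, 14 in Ursolic acid against Oleanolic Acid, 0 in Oxypaeoniflorin against Paeoniflorin, 1 in 6'-O-Galloyl paeoniflorin against Paeoniflorin and 13 in Picroside I against Catalpol among the rest of them. For the mean of the compounds the highest was 129 without the 3 deals that put that library among the vehicle libraries. The deals left, the real one included, are at most 20, too few for a share under 0.05. Any deal reaches a count of 0, so for results with a count of 0 by edgeR the 21 deals decide nothing, namely Albiflorin (0, 2581), Aucubin (0, 45), Benzoylpaeoniflorin (0, 53), Isoacteoside (0, 3162), 1,2,3,4,6-O-Pentagalloylglucose (0, 36), Catalpol (0, 2347), Mudanpioside C (0, 98), Ajugol (0, 43), Decursinol angelate against Decursin (0, 1836), Catalpol against Aucubin (0, 1599) and Senkyunolide A against Butylphthalide (0, 3).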

How the results depend on the processing

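The tests with a batch term, the vehicle libraries of the batch, the other compounds of the batch and without Chlorogenic Acid replicate 2 were chosen after the data were seen, and the others before. The cause of the moves below was not tested. Leave-one-out settings and fits of 2 groups use fewer samples, which does not account for counts that rose there. Without compound replicate 2, and in fits of 2 groups other than its own, replicate 2 of Chlorogenic Acid is also left out. Leaving out that library alone raised Rhmannioside D from 936 to 3175 calls, and the fit of 2 groups gave 2916. Without a filter more genes share the adjustment. The batch term compares compounds of batches 2, 4 and 5 with vehicle only through other batches, so a call lost there does not show that the compound had no effect.

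With DESeq2 counts moved by over 1.5 times as follows. Combinations with 1 adjustment had 15831, Rhmannioside D 2014, Ferulic Acid 1429, 7-Hydroxycoumarin 1042, Marmesin 849, Paeonolide 837 and Ursolic acid against Oleanolic Acid 749. Apiopaeonoside against Paeonolide had 680, Oleanolic Acid 519, Decursin 484, Jionoside B1 467, Oxypaeoniflorin 392, Picroside I against Catalpol 383 and Ursolic acid 367. Paeoniflorigenone had 318, Ligustilide A 298, Picroside I 288, Levistilide A 255, Vitamin E 244, Digoxin 231 and Apiopaeonoside 209. Purpureaside C had 206, 5-Hydroxymethyl-2-furaldehyde 180, Butylphthalide 149, Decursinol angelate against Decursin 136, Jionoside A1 128, D-Arabinose 88 and 1,2,3,4,6-O-Pentagalloylglucose and Hierochin D 69. Ajugol had 56, Nodakenin 38, Oxypaeoniflorin against Paeoniflorin 36, 6'-O-Galloyl paeoniflorin against Paeoniflorin 22, Decursinol angelate 19, 6'-O-Galloyl paeoniflorin 17 and Senkyunolide I, Mudanpioside C and Benzoylpaeoniflorin against Paeoniflorin 16. Senkyunolide A had 15, Catalpol 14, Albiflorin against Paeoniflorin 11, Benzoylpaeoniflorin 10, Benzoyloxypeoniflorin 9, Senkyunolide A against Butylphthalide 7 and Catalpol against Aucubin 6. Albiflorin, Aucubin and Isoacteoside had 3. With no filter on low counts counts moved by over 1.5 times as follows. Combinations with 1 adjustment had 4972, the mean of the compounds 4126, Rhmannioside D 294, Ursolic acid against Oleanolic Acid 156, Ferulic Acid 110, Picroside I against Catalpol 93 and 7-Hydroxycoumarin 48. Jionoside B1 had 41, Levistilide A 32, Apiopaeonoside against Paeonolide 29, Picroside I 25, Paeonolide 22, Paeoniflorigenone and Purpureaside C 15 and Decursin 13. Marmesin and Digoxin had 10, Vitamin E 9, Apiopaeonoside 7, Butylphthalide, Oleanolic Acid and Jionoside A1 6, Nodakenin and Oxypaeoniflorin 4, Hierochin D 2 and Senkyunolide I, 5-Hydroxymethyl-2-furaldehyde, Ligustilide A and Decursinol angelate 0. With the replicate number as a block counts moved by over 1.5 times as follows. Combinations with 1 adjustment had 4343, Rhmannioside D 294, 7-Hydroxycoumarin 167, Ferulic Acid 159, Marmesin 77, Ursolic acid 71 and Oleanolic Acid 58. Paeonolide had 51, Jionoside B1 48, Picroside I 42, Oxypaeoniflorin 39, Levistilide A 36, 6'-O-Galloyl paeoniflorin 18 and the mean of the compounds 13. Catalpol had 10, Mudanpioside C 9, Benzoyloxypeoniflorin and Ajugol 5, Catalpol against Aucubin 3, Paeoniflorin and Butylphthalide 2, Decursin, Ligustilide A and Decursinol angelate against Decursin 1 and Senkyunolide A, Senkyunolide I, 5-Hydroxymethyl-2-furaldehyde, Nodakenin and Decursinol angelate 0. In fits of the 2 compared groups alone counts moved by over 1.5 times as follows. Rhmannioside D had 2916, Ferulic Acid 2611, Marmesin 1725, 7-Hydroxycoumarin 1651, Paeonolide 1432, Apiopaeonoside against Paeonolide 1144 and Chlorogenic Acid 1114. Picroside I against Catalpol had 991, Oleanolic Acid 790, Oxypaeoniflorin 711, Jionoside B1 685, Decursin 635, Ligustilide A 505 and Digoxin 501. Levistilide A had 320, Apiopaeonoside 285, Picroside I 280, 5-Hydroxymethyl-2-furaldehyde 250, Paeoniflorigenone 165, Butylphthalide 128 and Vitamin E 118. Oxypaeoniflorin against Paeoniflorin had 115, Jionoside A1 96, Hierochin D 92, Purpureaside C 91, Catalpol against Aucubin 52, 6'-O-Galloyl paeoniflorin against Paeoniflorin 45 and Ursolic acid 23. D-Arabinose had 13, Senkyunolide I 12, Paeoniflorin and Ajugol 8, Mudanpioside C, Ursolic acid against Oleanolic Acid and Albiflorin against Paeoniflorin 3, 1,2,3,4,6-O-Pentagalloylglucose with 1 and Nodakenin and Benzoyloxypeoniflorin 0.

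With a batch term counts moved by over 1.5 times as follows. Any difference among compounds had 264, combinations with 1 adjustment 114, Decursinol angelate 85, Picroside I 46, 6'-O-Galloyl paeoniflorin 36, Chlorogenic Acid 32 and Paeoniflorin 19. Compounds with a call had 16, Paeoniflorigenone 15, Purpureaside C 11, Levistilide A, Vitamin E and Picroside I against Catalpol 7, Digoxin 4, Oxypaeoniflorin, Oleanolic Acid, 6'-O-Galloyl paeoniflorin against Paeoniflorin and combinations of list and compound 2 and Ajugol, Apiopaeonoside, D-Arabinose and the mean of the compounds 1. Senkyunolide A, Senkyunolide I, Butylphthalide, Decursin, 5-Hydroxymethyl-2-furaldehyde, Ligustilide A, Nodakenin, Benzoyloxypeoniflorin, Paeonolide, Rhmannioside D, Ferulic Acid, 7-Hydroxycoumarin, Marmesin, Hierochin D, Jionoside A1, Jionoside B1, Ursolic acid against Oleanolic Acid, Oxypaeoniflorin against Paeoniflorin and Apiopaeonoside against Paeonolide had 0. Against the vehicle libraries of the batch counts moved by over 1.5 times as follows. Decursinol angelate had 85, Picroside I 46, 6'-O-Galloyl paeoniflorin 36, Paeoniflorin 19, Paeoniflorigenone 15, Purpureaside C 11 and Vitamin E 7. Benzoyloxypeoniflorin had 0. Against the other compounds of the batch counts moved by over 1.5 times as follows. Chlorogenic Acid had 3259, combinations with 1 adjustment 1410, Paeoniflorin 68, Nodakenin 39, Decursin and Rhmannioside D 38, Ajugol and compounds with a call 19 and Oleanolic Acid 11. Butylphthalide had 8, Ferulic Acid 6, Benzoyloxypeoniflorin, Picroside I and combinations of list and compound 5, Purpureaside C 4, Ligustilide A, Oxypaeoniflorin, Levistilide A and Vitamin E 2 and Senkyunolide A, Senkyunolide I, 5-Hydroxymethyl-2-furaldehyde, 6'-O-Galloyl paeoniflorin, Paeonolide, 7-Hydroxycoumarin, Marmesin, D-Arabinose, Digoxin, Hierochin D, Jionoside A1, Jionoside B1 and Paeoniflorigenone 0. With a preset correlation 1 count moved by over 1.5 times. Combinations of list and compound had 282.

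Over all leave-one-out settings, the added one included, the lowest and highest counts were as follows. Albiflorin, Aucubin, Catalpol against Aucubin and Senkyunolide A against Butylphthalide had 0 to 0, Benzoylpaeoniflorin 0 to 1, Isoacteoside 0 to 3, Paeoniflorin 1 to 71, Senkyunolide A 1 to 34, Senkyunolide I 0 to 37 and Butylphthalide 0 to 460. Decursin had 3 to 1228, 5-Hydroxymethyl-2-furaldehyde 0 to 607, Ligustilide A 0 to 1031, Nodakenin 0 to 314, 1,2,3,4,6-O-Pentagalloylglucose with 0 to 215, Decursinol angelate 0 to 45 and Benzoyloxypeoniflorin 0 to 6. Catalpol had 0 to 9, 6'-O-Galloyl paeoniflorin 0 to 51, Mudanpioside C 0 to 15, Oxypaeoniflorin 1 to 1015, Paeonolide 0 to 1835, Rhmannioside D 54 to 3175 and Chlorogenic Acid 4771 to 8490. Ferulic Acid had 41 to 2596, 7-Hydroxycoumarin 24 to 2097, Marmesin 1 to 1815, Oleanolic Acid 1 to 1185, Ajugol 0 to 158, Apiopaeonoside 2 to 409 and D-Arabinose 0 to 243. Digoxin had 1 to 771, Hierochin D 1 to 105, Jionoside A1 1 to 268, Jionoside B1 37 to 984, Levistilide A 9 to 522, Picroside I 1 to 748 and Ursolic acid 1 to 881. Vitamin E had 3 to 549, Paeoniflorigenone 2 to 619, Purpureaside C 1 to 498, Ursolic acid against Oleanolic Acid 49 to 1407, Decursinol angelate against Decursin 0 to 394, Albiflorin against Paeoniflorin and Benzoylpaeoniflorin against Paeoniflorin 0 to 2 and Oxypaeoniflorin against Paeoniflorin 0 to 106. 6'-O-Galloyl paeoniflorin against Paeoniflorin had 0 to 11, Picroside I against Catalpol 13 to 779, Apiopaeonoside against Paeonolide 0 to 1473, the mean of the compounds 213 to 1381, any difference among compounds 2386 to 8829, combinations with 1 adjustment 4424 to 24833 and compounds with a call 25 to 36. Combinations of list and compound had 1 to 6.

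Some named genes turned direction. With the batch term they went, on the log2 scale, for Rhmannioside D Mrps28 to 0.23, Tap2 to 0.58 and Snrpf to 0.38, for Chlorogenic Acid Klhl41 to -0.54 and Napsa to -0.63, for Ferulic Acid Sdhd to 0.20, Snrpf to 0.57 and Rerg to 0.26, for Apiopaeonoside against Paeonolide Map1lc3a to 0.18. Against the other compounds of the batch they went, on the log2 scale, for Chlorogenic Acid Bco1 to -0.25, for Oleanolic Acid Emc1 to -0.0106. Cep295 in Ursolic acid against Oleanolic Acid ran from -0.00216 (without compound replicate 2) to 4.27 over the leave-one-out settings. Of 186 combinations of a named gene and a comparison (128 genes), some were no longer called, with direction kept. These were 50 with no filter, 70 with the block and 163 with the batch term. They were 72 without compound replicate 1, 45 without compound replicate 2, 91 without compound replicate 3 and 9 without Chlorogenic Acid replicate 2. Against the vehicle of the batch 13 were no longer called and 7 were kept, and the rest were not tested there. Against the other compounds of the batch 128 were no longer called, 21 were kept and 2 turned direction, and the rest were not tested there. With DESeq2 174 were tested and kept.

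Samples that share a replicate number had a mean correlation of residuals of -0.00292 and those with different numbers 0.00215; 17.3% of same-number pairs exceeded 0.1, and 31 of 114 libraries were closest to their own number. The samples share only a number, which does not pair them, so the counts above with that number as a block are not those of a paired analysis.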

Other observations

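Akr1b7, an aldose reductase relative of steroid-producing cells, averaged 70.8 ± 65.0 CPM (SD, n = 10) in vehicle and reached 897 CPM in replicate 2 of Ajugol, and it was at 0.882 CPM in replicate 1 of Nodakenin, 0.635 in replicate 2 of 1,2,3,4,6-O-Pentagalloylglucose, 0 in replicate 1 of Decursin, 0.438 in replicate 1 of D-Arabinose, 0.569 in replicate 2 of Jionoside B1 and 0.910 in replicate 3 of Chlorogenic Acid. These 6 libraries were picked for a level under 1 CPM after the values were seen, and the doubted replicate 2 of Chlorogenic Acid, at 0 CPM, is left aside. In the 6 libraries the LH receptor gene Lhcgr stood at 197, 476, 651, 927, 829 and 589 CPM, on both sides of the vehicle range of 213 to 642 CPM. Aromatase, Cyp19a1, stood at 11.2, 59.5, 21.5, 31.1, 16.9 and 14.4 CPM in the same order, of which 3 lie within the vehicle range of 0.213 to 17.2 CPM.

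Markers of other tissues were seen in single libraries or batches, and these markers were chosen after their values were seen. The melanocyte gene Tyrp1 was highest with Dct in replicate 1 of Purpureaside C, at 1.34 CPM. Transcripts of astrocytes were highest in vehicle replicate 5 of batch 3, with the glutamate transporter Slc1a2 at 13.9 CPM and Gfap at 5.69. Transcripts of hair were highest in vehicle replicate 9 of batch 6, with trichohyalin Tchh at 21.2 CPM, Krt25 at 9.48 and Krt81 at 12.9. The compounds of a batch, as a set against the vehicle libraries of that batch, differed in 2 genes in batch 1, in 9 in batch 3 and in 131 in batch 6. In batch 1 these were the neurofilament genes Nefl (log2 -5.33 ± 0.74, adjusted p = 8.69e-06) and Nefm (log2 -4.43 ± 0.72, adjusted p = 0.000570). Both lay near the floor, at 1.09 and 1.11 CPM on average over all vehicle libraries, with a median of 0 over all libraries. In batch 3 the genes included Tef (log2 0.60 ± 0.11, adjusted p = 0.00863) and the co-chaperone Dnajb1 (log2 -0.62 ± 0.11, adjusted p = 0.00863). In batch 6 114 of the 131 genes were lower in the compounds, and Tchh had the smallest adjusted p (log2 -3.30 ± 0.29, adjusted p = 5.3e-15). Krt25, Cst6, Krt81 and Klk7 came next, also lower. Tchh and these genes each had their highest level of all libraries in vehicle replicate 9.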
